A study of Rattus norvegicus with 12 samples.

How the data were processed

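Poly(A)-selected RNA was sequenced from trigeminal ganglia (TG) and dorsal root ganglia (DRG) of 6 naive male Wistar Han rats on an Illumina HiSeq, per the labels' protocols. The animals were 10 weeks old and were killed 2 weeks after arrival, following perfusion with cold saline to remove blood. Each rat gave 1 library per ganglion type, so that there were 6 TG and 6 DRG libraries. The labels do not state which spinal levels the DRG came from or whether ganglia of both sides were combined.

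The authors deposited 1 table of read counts per library. Per the submitters' processing notes, STAR and HTSeq were used with the rat genome build Rnor_6.0. The versions, the annotation release and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes cannot be assumed to have been told apart. The counts were whole numbers for 32662 Ensembl gene identifiers, followed by 5 rows of reads given to no gene. Those 5 rows (reads outside annotated genes, reads overlapping more than 1 gene, reads aligned to several places, and 2 rows at 0) were left out of library sizes and of tests between genes. They held 15.7% to 16.9% (outside genes), 1.42% to 1.49% (more than 1 gene) and 12.3% to 13.2% (several places) of the reads in the DRG files, and 20.5% to 21.0%, 1.39% to 1.46% and 11.4% to 11.9% in the TG files. Reads from near-identical gene copies fall in the last class and are missing from the counts of those genes.

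The deposited tables list identifiers without gene symbols. None of the 32662 identifiers (0) was found in the reference table of rat genes used here. The 41 gene lists and the genes chosen by name before the data were examined were therefore not analysed here, and neither were checks of GC content and gene length. The rule for naming genes was to take those with the largest fold change in each direction among genes with an adjusted p under 0.05, the same sign in all 6 rats and a mean of at least 1 CPM (counts scaled to the size of the library) in the higher tissue. It left out identifiers without a symbol, and it also named members of the gene lists, a fixed set of genes and the 5 most abundant genes. With no symbols, the first 2 identifiers in each direction were reported under the same conditions, and abundant genes are given by rank.

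Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr by tissue (14554 genes, holding 99.9% of the counts in genes), scaled with TMM factors and tested with the quasi-likelihood test with robust estimation, tissue being the only term. P-values were adjusted with the Benjamini-Hochberg method and called under 0.05. Fold changes are TG relative to DRG. Standard errors were taken as the absolute log2 fold change divided by the square root of the F statistic, and 95% intervals from the corresponding t quantiles. A gene was called within 2-fold when its whole interval lay inside a 2-fold change either way. CPM were computed from TMM-scaled libraries, and log2 CPM with a prior count of 2. A gene was called restricted to a tissue by a definition made after the data were seen. It had to reach 1 plain CPM (without TMM factors) in all 6 libraries of that tissue. At most 3 counts were allowed over the 6 libraries of the other tissue. A floor of 3 counts over the 6 libraries was used for genes with 0 counts. Intervals and floors from counts cover counting error only. Measures of whole libraries were compared with exact two-sided permutation tests, adjusted over the 7 measures. For detected genes, each library was thinned at random to the 11876597 counts of the shallowest one.

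Both libraries of a number came from the same animal, so the numbers pair the samples. The 2 libraries of a rat deviated from their tissue means together, with correlations across genes of 0.23 to 0.34, against -0.14 to 0.10 for libraries of different rats. Each of the 6 TG libraries correlated best with the DRG library of its own rat. No other of the 720 pairings gave a mean correlation as high (exact permutation p = 0.0014, one-sided). A fit with the rat as a block was an alternative fixed in advance. Between libraries of a tissue, counts varied 4.0 to 13.3 times more than sampling alone gives, so no library was a copy of another.

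Libraries held 11876597 to 17184211 counts in genes. On data simulated from the real means of these libraries (14502 genes passing the filter), the TG and DRG test called 86% of genes changed by 1.5-fold and 100% of those changed 2-fold, 4-fold or 8-fold, and 0.038% of unchanged genes. All genes were simulated with the same dispersion (spread between libraries). The changed genes had at least 20 counts per library on average, so their shares hold for such genes at that dispersion. The share of unchanged genes was taken over genes of all levels, with few changed genes beside them. It therefore does not give the rate of false calls in the real data. The tests of variability, of rat-dependent genes and of co-varying genes were also tested on simulated data. Alternatives fixed in advance were other scaling (DESeq2 size factors, upper quartile), other filters, DESeq2 1.42.0, limma-voom with limma 3.58.1, a test against a fold of 1.5, a threshold of 0.01, the block, and leaving out each rat or library.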

Results

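The transcriptomes of 2 kinds of sensory ganglia were compared in the same animals. TG hold the cell bodies of sensory neurons of the face and head, and DRG those of the trunk and limbs, each together with glia, vessels and connective tissue. The 12 libraries came from 6 male Wistar Han rats, an outbred laboratory strain, and each rat gave 1 TG and 1 DRG library. TG libraries held 13564770 ± 1134435 counts in genes (SD, n = 6) and DRG libraries 15086357 ± 1544684, a difference that did not pass an exact permutation test (two-sided p = 0.078, adjusted 0.078). Genes are given by their Ensembl identifiers, because the deposited tables do not pair them with symbols.

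The tissue was the main difference between the libraries. The first principal component of log2 CPM held 66.1% of the variance and put all 6 TG libraries on one side and all 6 DRG libraries on the other. The second component held 6.02%. The 2 ganglia were nevertheless close in mean level, with a Pearson correlation of 0.96 across the 14554 tested genes, which are not independent replicates. The 5 genes with the highest mean level were the same order of magnitude in both tissues. The most abundant of them was at 17651 ± 2255 CPM in TG and 18206 ± 1583 CPM in DRG (SD, n = 6), with a log2 fold change of -0.04 and a 95% interval of -0.23 to 0.14. The next was at 12905 ± 880 CPM in TG and 11975 ± 652 CPM in DRG, with a log2 fold change of 0.11 (95% interval 0.01 to 0.21). The genes at ranks 3, 4 and 5 were also higher in TG, with log2 fold changes of 0.29, 0.23 and 0.17 and intervals above 0.

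More genes were detected in TG than in DRG at equal depth. With each library thinned to the size of the shallowest, 18778 ± 90.8 genes had at least 1 count in TG and 18249 ± 35.4 in DRG (SD, n = 6), higher in TG in 6 of 6 rats. At least 1 plain CPM was reached by 14186 ± 88.0 genes in TG and 13944 ± 55.4 in DRG. The TMM factors, not used for this count, were 1.006 to 1.024 in TG and 0.979 to 0.994 in DRG, so plain CPM favoured TG. The 10 most abundant genes of a library took 9.30% ± 0.28 of the counts in TG and 8.14% ± 0.24 in DRG. Reads outside annotated genes made up 20.8% ± 0.26 of the reads in the TG files and 16.3% ± 0.44 in the DRG files, and reads aligned to several places 11.6% ± 0.19 and 12.6% ± 0.32. Each of these 5 differences separated the tissues without overlap, in the same direction in 6 of 6 rats (exact permutation test, two-sided p = 0.0022, the smallest that 6 libraries against 6 can give; adjusted p = 0.0030 over 7 measures). The share of reads overlapping more than 1 gene, 1.42% ± 0.029 in TG and 1.45% ± 0.025 in DRG, did not pass (exact permutation p = 0.065, adjusted 0.076).

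**Figure D1:**
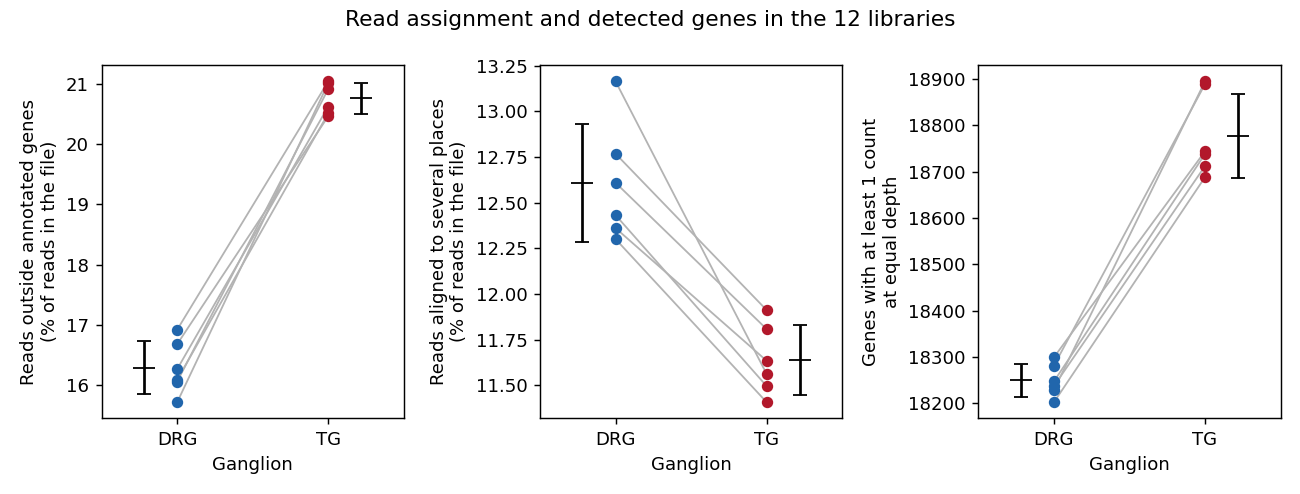
Share of reads outside annotated genes (% of reads), share of reads aligned to several places (% of reads) and number of genes with at least 1 count at equal depth, for the 6 DRG (blue) and 6 TG (red) libraries. Grey lines join the libraries of a rat, black bars show the mean ± SD, and the axes do not start at 0. In each panel the tissues do not overlap: the share outside genes was 15.7% to 16.9% in DRG and 20.5% to 21.0% in TG.

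More than 50% of the tested genes differed between TG and DRG, most of them by a small amount. Of 14554 genes, 8341 (57.3%) passed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 4354 higher and 3987 lower in TG. The median absolute log2 fold change of these genes was 0.39, and 85.3% of them changed by less than 2-fold. The sign was the same in all 6 rats for 7297 of the 8341 genes. The lowest library of one tissue lay above the highest of the other for 5265 genes (36.2%). Chance gives 0.22% if all 12 libraries are exchangeable, which leaves the pairing by rat out of account.

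Changes of at least 2-fold were found for 1222 genes, 677 higher and 545 lower in TG. The genes higher in TG took 2.89% of the counts in TG and 1.05% in DRG, and those lower in TG took 1.24% in TG and 3.22% in DRG. Such changes were most frequent among weakly expressed genes. They were seen in 19.8% of the 410 tested genes with a mean under 1 CPM and in 16.9% of the 4224 genes at 1 to 10 CPM. The share was 4.53% of the 7747 genes at 10 to 100 CPM and 3.55% of the 2085 genes at 100 to 1000 CPM. Only 3 of the 88 genes above 1000 CPM changed by at least 2-fold, 2 higher and 1 lower in TG. Under 1 CPM, 54 genes were at least 2-fold higher and 27 lower in TG, and at 1 to 10 CPM 435 were higher and 278 lower. Between 10 and 100 CPM the counts were 160 higher and 191 lower, and between 100 and 1000 CPM 26 higher and 48 lower. Precision also depended on level, with a median standard error of the log2 fold change of 0.16 at 1 to 10 CPM and 0.04 at 100 to 1000 CPM. At least 4-fold, 128 genes were higher and 96 lower in TG, at least 8-fold, 58 were higher and 37 lower, and at least 16-fold, 33 were higher and 21 lower. At least 32-fold, 14 were higher and 17 lower, or 16 lower when the 6 of them with 0 counts in TG are set to the floor of 3 counts. Over the 6 TG libraries, 97 of the 677 genes moved together (correlation above 0.9 of log2 CPM with ENSRNOG00000031927, that gene included). This group held 45 of the 128 genes at least 4-fold higher, 33 of the 58 at least 8-fold and 22 of the 33 at least 16-fold. Without it 83, 25 and 11 genes were higher at these folds, against 96, 37 and 21 lower. The group was chosen among genes higher in TG only, and no genes were left out on the other side. The change in balance therefore follows from this choice and does not compare the tissues. In the DRG library of rat R103, 30 genes were more than 4-fold above all other DRG libraries, and 11 of these were among the genes that changed.

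**Figure D2:**
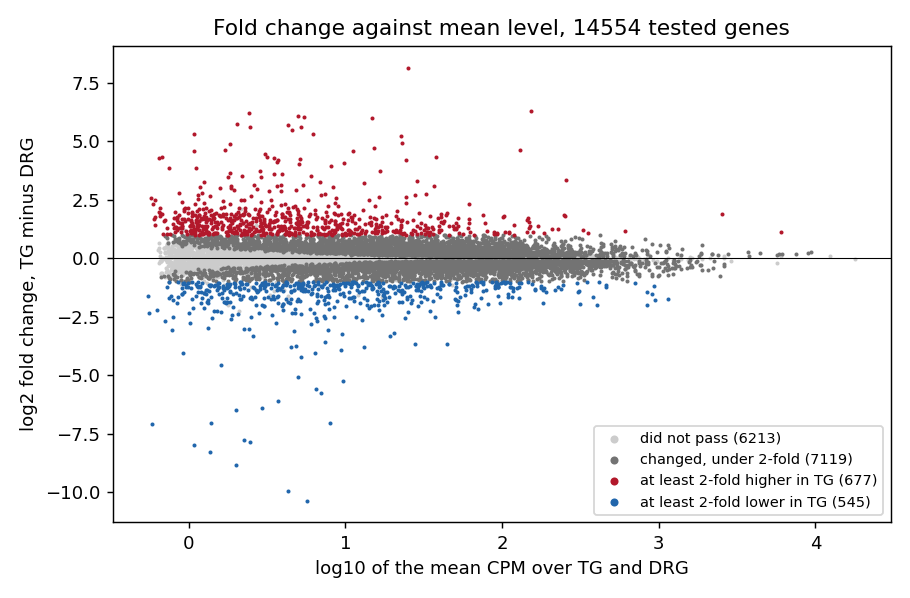
Log2 fold change (TG minus DRG) of each of the 14554 tested genes against the log10 of its mean CPM over both tissues. Red points are the 677 genes at least 2-fold higher and blue points the 545 genes at least 2-fold lower in TG, dark grey points passed with a smaller change, and light grey points did not pass. Genes with 0 counts in one tissue are drawn at their fitted value, which depends on the prior count. Changes of at least 2-fold were more frequent at low level, in 16.9% of genes at 1 to 10 CPM and 4.53% at 10 to 100 CPM.

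For most genes a difference of 2-fold or more could be excluded. The 95% interval of the fold change lay within 2-fold for 12256 genes (84.2%), and 6380 of these also passed the test for a difference. With a bound of 1.5-fold, 9521 genes lay within it.

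A few genes were found in one tissue with almost no counts in the other. By a definition made after the data were seen, 9 genes were restricted to DRG, 5 of them with 0 counts in TG. All 9 had at least 1 plain CPM in all 6 DRG libraries and at most 3 counts over the 6 TG libraries. Their median level in DRG was 4.01 CPM and the highest 11.4 CPM. No gene (0) met the same definition for TG. The division of 9 against 0 had a p of 0.0039 in an exact two-sided binomial test, which treats genes as independent. The limit of 3 counts was not scaled to depth. It was easier to meet in TG, whose libraries held 13564770 counts on average against 15086357 in DRG. The excess on the DRG side depended on this limit. With at most 10 counts allowed in the other tissue, 12 genes were restricted to DRG and 5 to TG (exact binomial p = 0.14), and with 0 counts allowed 5 and 0 (exact binomial p = 0.062).

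The largest decreases and increases in TG are given for 2 identifiers each. ENSRNOG00000028619 was at 11.4 ± 1.51 CPM in DRG (SD, n = 6) and had 0 counts in all 6 TG libraries. With counts summed over the libraries of a tissue and a floor of 3 counts for TG, it was at least 311-fold lower in TG (edgeR, adjusted p = 2.1e-10). ENSRNOG00000007611 was at 8.62 ± 0.66 CPM in DRG, also with 0 counts in TG. At the same floor it was 237-fold lower there (edgeR, adjusted p = 1.6e-10), and the lower limit of its ratio was 193. ENSRNOG00000031927 was at 50.1 ± 19.2 CPM in TG and 0.17 ± 0.14 CPM in DRG, a log2 fold change of 8.15 ± 0.51 (SE; edgeR, adjusted p = 1.2e-07). ENSRNOG00000018700 was at 303 ± 157 CPM in TG and 3.90 ± 1.62 CPM in DRG, a log2 fold change of 6.30 ± 0.52 (SE; edgeR, adjusted p = 1.8e-06). In TG, its level ranged from 110 CPM (rat R106) to 482 CPM (rat R102), and that of ENSRNOG00000031927 from 25.9 CPM to 73.4 CPM in the same animals. All 4 identifiers had the same sign in 6 of 6 rats, which was a condition for reporting them. Their chromosomal positions were not used here, as the reference table used here follows another genome build.

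**Figure D3:**
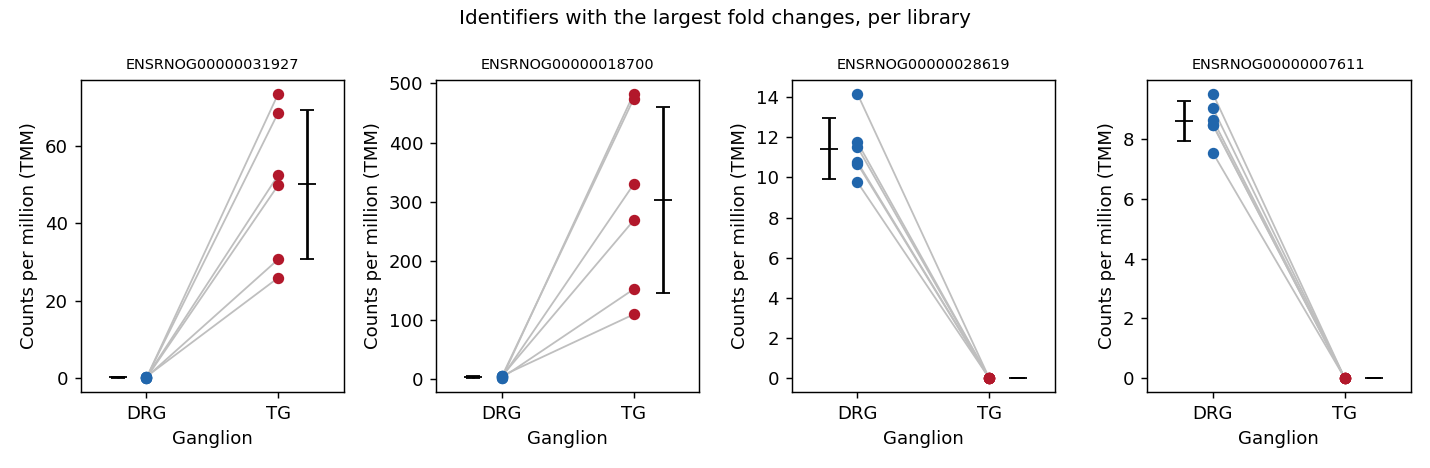
TMM-scaled CPM of the 2 identifiers with the largest increase and the 2 with the largest decrease in TG, for 6 DRG (blue) and 6 TG (red) libraries. Grey lines join the libraries of a rat, black bars show the mean ± SD, and each panel has its own axis starting near 0. Both identifiers lower in TG have 0 counts in every TG library, and both higher in TG spread widely between TG libraries (25.9 to 73.4 CPM and 110 to 482 CPM).

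Variability between rats was compared between the tissues. The median SD of log2 CPM over the 6 rats was 0.12 in TG and 0.11 in DRG, and 56.2% of the genes were more variable in TG. Swapping the tissue labels within rats gave a share as far from 50% in 7 of 32 splits, the real one included (exact permutation p = 0.22, two-sided). Swapped groups mix the tissues and carry the tissue difference as spread. These splits therefore do not decide whether the tissues differ in variability.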

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

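Of 22 sets of 6 libraries examined for a sample far from the others, 1 stood out, where chance gives about 1 in 20. The set was the number of genes more than 4-fold above every other library of the same tissue, a measure added after the data were seen. It was 30 genes in the DRG library of rat R103 and 0 in each of the other 5 DRG libraries. With 5 values at 0, any count above 0 would have stood out, so the rate of 1 in 20 does not hold for this set. These 30 genes had a median of 23.6 CPM in that library and 1.79 CPM over the others, reached 172 CPM, and took 0.10% of its counts. None (0) of them stood out in the same way in the TG library of that rat. In TG, the library of rat R104 had 16 such genes and that of rat R105 had 7. Without the DRG library of rat R103 and the TG library of rat R104, 7903 genes changed between the tissues, 703 of them at least 2-fold higher and 571 at least 2-fold lower in TG.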

How the results depend on the processing

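All 4 reported identifiers kept their direction and passed in each of 28 alternatives, their largest adjusted p being 7.5e-04 (limma-voom, ENSRNOG00000031927). Leaving out the DRG library of rat R103 and the TG library of rat R104 together, and other count limits for restricted genes, were chosen after seeing the data. The counts of changed genes (8341) and of genes changed at least 2-fold (1222) stayed within 1.5 times in 27 of 28 alternatives each. The exceptions were the test against a fold of 1.5, which by its construction called 1507 genes, 846 higher and 661 lower in TG, and the fit without a low-count filter. That fit tested 23184 genes and called 2131 changed at least 2-fold, 1352 of them higher and 779 lower in TG. The fit with the rat as a replicate block called 8834 genes, 675 at least 2-fold higher and 551 at least 2-fold lower in TG, with 12414 within 2-fold, and changed no call of a reported identifier. Leaving out a rat gave 7702 to 7903 changed genes (4019 to 4107 higher, 3679 to 3836 lower), 1204 to 1272 changed at least 2-fold and 12076 to 12197 within 2-fold, and leaving out a library 7969 to 8210 changed genes. The excess of genes higher in TG (4354 against 3987 lower) depended on the scaling: it was 4181 against 4150 with DESeq2 size factors and 4504 against 3858 with upper-quartile factors. DESeq2 called 8137 genes, 4076 higher and 4061 lower. Exact sign flips within rats gave p = 0.031 (adjusted 0.044) for the 5 measures of libraries that differed. The share of genes more variable in TG was 52.6% to 59.0% when a rat was left out, and did not pass. The swaps do not decide this, since swapped groups mix the tissues, and with 5 rats they cannot give a p under 0.05. The 9 genes restricted to DRG became 5 with a limit of 0 counts, and the 0 restricted to TG became 5 with a limit of 10 counts, by the construction of the limits. The tests of gene lists and the GC and length corrections were not run, as no identifier had a symbol or annotation here. Precision was lowest for weakly expressed genes, with a median standard error of the log2 fold change of 0.28 for the 410 tested genes under 1 CPM and 0.16 at 1 to 10 CPM; depth and variation between rats were not separated as its source.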

Other observations

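The tests of reads outside annotated genes, of genes switched off in a rat, of sequence variants, of slopes of all genes at least 8-fold higher in TG and of each gene changed at least 8-fold as a lead were chosen after the results had been seen. The other tests were written before their own results, although the co-varying genes, the rat-dependent genes and their lead measure had already been noticed in the same data.

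Genes strongly higher in TG rose and fell together between TG libraries. Taking ENSRNOG00000031927, the gene with the largest increase, as a lead, 96 of the other 676 genes at least 2-fold higher in TG had a correlation above 0.9 with it over the 6 TG libraries. Their share grew with the fold change, from 14.2% of genes at least 2-fold higher to 34.6% at least 4-fold. It was 56.1% at least 8-fold and 65.6% at least 16-fold, against 2.16% of all tested genes. The median SD of log2 CPM over the TG libraries grew over the same sets (0.28, 0.49, 0.69 and 0.75). Fold change and spread were therefore not told apart in this trend. With each of the 58 genes at least 8-fold higher in TG as a lead in turn, the median number of genes with a correlation above 0.9 was 75 of 676 (lowest 1, highest 110). With each of the 37 genes at least 8-fold higher in DRG as a lead in DRG libraries, it was 4 of 544 (lowest 0, highest 16). The median SD of log2 CPM within the higher tissue was 0.69 for genes at least 8-fold higher in TG and 0.36 for those at least 8-fold higher in DRG, so the 2 tissues were not compared at equal spread. The 97 genes of the group, lead included, took 1.63% of the counts in TG and 0.58% in DRG. A large part of the share in TG came from 1 gene, at a mean of 8271 CPM in TG.

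For this group, coincidence of 6 libraries was tested by permuting the order of the lead's libraries: 1 of 720 orders, the real one, gave as many genes, and the highest other order gave 95. Library scaling is argued against, since the median gene moved by 0.042 on the log2 scale of plain CPM between TG libraries, while the 32 group genes at least 8-fold higher moved by 1.81 (3.51-fold). A difference between rats shared by both ganglia is argued against for the 35 group genes with at least 5 CPM in DRG, whose TG and DRG levels had a median same-rat correlation of -0.073 (quartiles -0.43 and 0.16). The hypothesis that a tissue or cell type is present in TG dissections in varying amounts predicts that its genes move by the same factor; the 32 genes had a median slope of 1.13 on the lead (quartiles 0.98 and 1.23). These genes were chosen by their correlation with the same lead, so their slopes do not decide it. Over all 57 genes at least 8-fold higher in TG besides the lead, these 32 included, the median slope was 0.99 (quartiles 0.48 and 1.21), and the explanation stays open. A regulated change within TG that differs between rats was not tested and stays open, and the cell type was not examined.

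Some genes differed between rats alike in both ganglia, and their overlap with the co-varying TG group was not examined. In the fit with rat and tissue, 533 genes depended on the rat at an adjusted p under 0.05 (edgeR), 261 of them also changed between the tissues, and 49 differed by at least 4-fold between the highest and the lowest rat. Coincidence of pairing was tested by joining TG libraries with DRG libraries of other rats: 1 of 40 pairings, the real one, gave as many genes, and the highest other gave 3. Of the 533, 8 genes were switched off in a rat, judged on plain CPM. They had at least 1 CPM in both ganglia of 3 or more rats and at most 0.1 CPM in both ganglia of another. Re-paired libraries gave at most 1 such gene. Re-pairing parts a shared batch as well as a shared rat, so it bears on coincidence only. These 8 genes argue against a preparation batch shared by the 2 libraries of a rat only if a batch cannot bring expressed genes to 0.1 CPM. That assumption was made after the results had been seen and was not tested. For the remaining genes, whose change is mostly small (median 1.54-fold between the highest and the lowest rat over the 533), a shared batch stays open. Sequence variants of the rats against the reference genome cannot be told apart from expression for any of the 533, because counts per gene hold no position along the gene.

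The larger share of reads outside annotated genes in TG (4.48 percentage points) was examined for 2 technical explanations. Sequencing depth is argued against: among the 7 pairs of a TG and a DRG library with total reads within 5%, the smallest difference was 4.0 points, above the range within either tissue (0.58 in TG, 1.21 in DRG). The co-varying TG group is argued against as the whole cause, since a share proportional to its level would range over 5.18 points between TG libraries and the observed range was 0.58 points. The share and the group level had a Pearson r of 0.80 over the 6 TG libraries (exact permutation p = 0.069; Spearman rho 0.66, exact permutation p = 0.18; r = 0.61 without the 2 libraries farthest from the median level), so a small contribution stays open. A difference between the tissues in unspliced or unannotated transcripts was not tested and could also account for it.

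Chance as the source of the tissue differences was examined by regrouping the libraries. Of 100 splits into 6 and 6, 1, the real one, gave as many as 8341 changed genes, and the highest other gave 60. For genes changed at least 2-fold, 1 of 100 splits gave as many as 1222, and the highest other gave 18. Of the 32 splits that part every rat's libraries, 1, the real one, gave as many changed genes, and the highest other gave 0. For the counts of changed genes and of genes changed at least 2-fold, no other split examined came as high. Shares of 1 in 100 and 1 in 32 are the smallest that these splits can give. Mixed splits carry the tissue difference as spread within their groups, so their low counts do not give the number of calls expected by chance. For the share of genes more variable in TG, 7 of 32 splits were as far from 50% as the real 56.2%, and the farthest other was at 59.4%. The other splits mix the tissues here too, so they do not decide whether the tissues differ in variability. For genes within 2-fold, 1 of 100 splits gave as few as 12256, and the lowest other gave 12432; mixed splits carry the tissue difference within their groups, so these splits do not bear on how alike the tissues are.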
